A study of Mus musculus with 66 samples.

How the data were processed

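Lung RNA was hybridised to Affymetrix mouse arrays, 1 array for each of 66 samples, in 22 groups of 3 (2 genotypes at 11 ages). Genotype, age and replicate number were taken from the sample titles and characteristics. The labels call the samples of a group biological replicates, and the RNA came from separate lungs or, at E13.5, from 2 to 3 combined lungs.

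The values analysed were the deposited intensities, 1 linear signal per probe set and array, made with GCOS per the submitters' processing notes. Its version, the algorithm and the scaling target were not given in the sources used here. The deposited values of 42 arrays had a 2% trimmed mean of 500 and those of the 24 arrays of PND1 to PND4 did not, so the 2 sets were scaled differently before deposit. Scanner files were not used here.

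Of 45101 probe sets, the 64 controls were left out of the tests, which left 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160, and only probe sets with 1 symbol were named. The GRCm38.p6 gene table was used for current symbols and for the order of genes along chromosomes, and no coordinates were taken from it. Where a gene had several probe sets, the one with the highest mean over all samples stood for it, which gave 18193 genes.

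Because the array medians ranged from 40.6 to 127.4, values were quantile normalized between arrays and analysed as log2(value + 16). Fold changes are on this scale, so they understate changes of dim genes. Within groups the lowest correlation between 2 arrays was 0.9264, and the highest between any 2 arrays was 0.9834, so no 2 arrays were identical.

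One limma model (version 3.58.1, in R 4.3.3 with data.table version 1.17.8) with a mean for each of the 22 groups was fitted to all 66 arrays, with empirical Bayes moderation and an intensity trend (residual df 44, prior df 6.69). All groups shared the estimate of spread, because 3 against 3 alone leave few degrees of freedom. Contrasts were the knockout minus wild-type difference averaged over the ages and at each age, an F test of whether that difference was equal at the 11 ages, an F test of age in wild type, 3 age steps in each genotype, and the difference of each step between genotypes. P-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets of a contrast, with a threshold of 0.05, and are two-sided. An exact permutation test of 3 against 3 cannot give a p under 0.1, so none was used for single ages.

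Gene lists, the choice of tests, the main settings and most alternatives were fixed before the data were examined. Of 36 lists with 491 entries, 446 entries were measured, and 35 lists were tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, and with fry. List p-values were adjusted over the 35 lists of a contrast. In every list that passed, the median, the mean and the directions of camera and fry had the same sign. List members were also counted after adjustment over the list alone.

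Named genes followed a rule: all Nfe2l2 probe sets; for the average over ages, the 12 largest rises and falls of the same sign at 9 or more of 11 ages; at each age, the 2 largest rises and falls in which all 3 knockout values lay beyond all 3 wild-type values; the 10 smallest p for the dependence on age; the 12 largest rises and falls of each wild-type step and the 3 largest of each difference between steps; and list members. Predicted loci and sex-linked genes were passed over.

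The model was tested on simulated data made from the 45037 real probe sets. Noise was normal and drawn independently for each probe set, with its residual SD. Correlation between genes and libraries that stand apart were not simulated, so the error rates given here do not cover them. For the average over ages it recovered 98.5% of probe sets changed by 0.5 and 100% of those changed by 1, with 9.3% of its calls false. For a single age (E18.5) it recovered 34.3%, 80.6% and 97% at 0.5, 1 and 2, with 3.9% false, and for the dependence on age 1.5%, 47.8% and 92.4%, with 4.9% false. A planted shift of -0.5 in the Nrf2 target list was found in both comparisons tested (adjusted p = 1.7e-162 and 2.8e-30), and 2 and 0 of 34 other lists were called.

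Alternatives covered the normalization, the pseudocount, a filter on dim probe sets, the variance model, array weights, the groups in the fit, the replicate number as a block, 1 probe set per gene, Xist level, the ratio of 3' to 5' Gapdh control signals, leaving out each library in turn, and, chosen after seeing the data, other scalings, other sets of ages and other end ages of the steps. The estimated correlation was run for every list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.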

Results

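RNA from homogenized mouse lung was measured on 66 one-colour Affymetrix arrays, 1 array per sample. The samples formed 22 groups of 3, wild type (Nrf2+/+) and knockout (Nrf2-/-) at 11 ages: embryonic days E13.5, E15.5, E17.5 and E18.5 and postnatal days PND0, PND1, PND2, PND3, PND4, PND14 and PND42. Nrf2, the product of Nfe2l2, is a transcription factor that switches on antioxidant and detoxification genes. Per the labels, 2 to 3 lungs were combined in each sample at E13.5, and each other sample was 1 lung. The deposited signals ran from 0.0326 to 61022, and 45037 probe sets that are not controls were tested, which stood for 18193 genes. The number of arrays, 3 per group, limited the precision. Each SE below comes from the spread pooled over all 22 groups, so it can understate the spread where the libraries of a group were unlike.

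The arrays came in 2 sets that followed age. At PND1 to PND4 the 24 arrays had 2% trimmed mean signals of 171.7 to 307.14 and medians of 40.598 to 81.331. The 42 arrays of the 7 other ages all had a trimmed mean of 500 and medians of 85.16 to 127.43. Both genotypes of every age lay within 1 set, so the genotype comparisons at each age did not cross it, while comparisons between PND4 and E18.5 or PND42 did. All values below are differences on the log2(signal + 16) scale after quantile normalization, which understates changes of dim genes. In several comparisons the share of calls that were higher depended on the scaling.

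**Figure D1:**
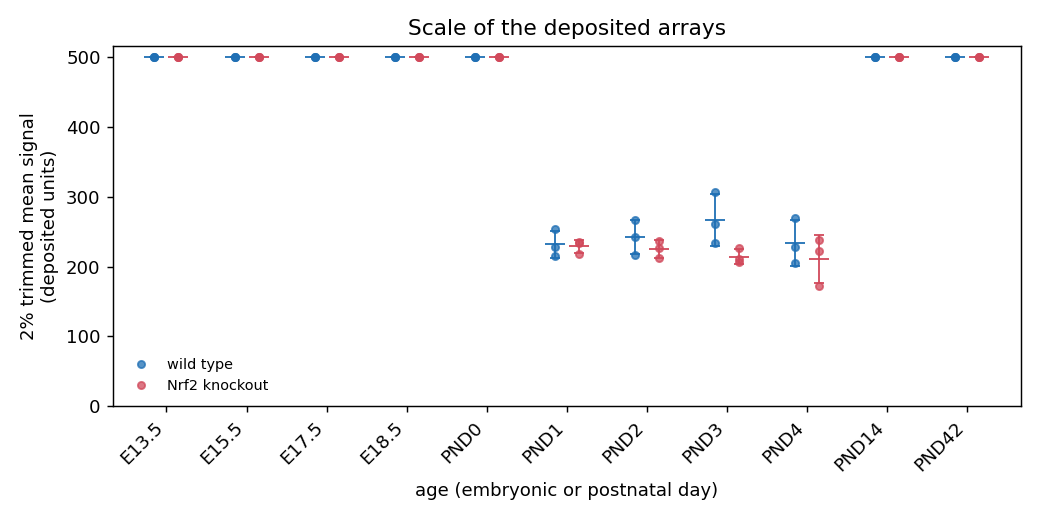
The 2% trimmed mean of the deposited signal (vertical axis, deposited units) is plotted for each array against age, with wild type in blue and knockout in red, bars for the mean and SD of 3 arrays. The arrays of PND1 to PND4 lie between 171.7 and 307.14 and all others at 500.

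The targeted gene was examined first, because it checks the genotype labels. The brighter Nfe2l2 probe set lay between 10.49 and 12.25 in the 33 wild-type libraries and between 4.41 and 8.26 in the 33 knockout libraries, so no knockout library reached the wild-type range. Averaged over the ages it was 75-fold lower in knockouts (log2 difference -6.23 ± 0.10, SE, n = 33 per genotype, adjusted p = 4.1e-44, limma). The difference was smallest at E13.5 (-3.82 ± 0.34, n = 3 per group), where the knockout libraries stood at 8.26, 5.43 and 6.76, and largest at E17.5 (-6.91 ± 0.34). A dim second Nfe2l2 probe set did not follow the genotype in this way, with an average difference of 0.51 ± 0.09 (adjusted p = 0.00013), 3.27 at PND0 and -1.93 at PND1.

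Averaged over all ages, antioxidant and detoxification genes fell in knockouts. The average does not mean a fall at every age. At E13.5 the means of the Nrf2 target list overlapped (9.13, 8.81 and 8.96 in knockouts, 9, 8.99 and 9.07 in wild type). Among the strongest falls after Nfe2l2 were Gsta3, a glutathione S-transferase (-1.43 ± 0.11, SE, n = 33 per genotype, adjusted p = 7.8e-14), Gpx2, a glutathione peroxidase (-1.29 ± 0.13, adjusted p = 1.8e-10), and the aldehyde oxidases Aox1 (-0.96 ± 0.08) and Aox3 (-0.86 ± 0.08). Arg1, an arginase (-0.91 ± 0.17), Niban1 (-0.82 ± 0.07) and the nuclear non-coding RNA Malat1 (-0.73 ± 0.07) fell as well. Rbm45, an RNA-binding protein gene, rose most (2.06 ± 0.07, adjusted p = 7.4e-28). Rbbp9 (0.76 ± 0.11), Scnn1a, an epithelial sodium channel subunit (0.60 ± 0.08), Usp38 (0.55 ± 0.05) and Stom (0.53 ± 0.04, with 1 of 5 other probe sets) rose too. Rbm45, Cyct (-0.74 ± 0.11) and Fam171b (-0.97 ± 0.10) lie among the 100 measured genes nearest Nfe2l2 in the GRCm38.p6 gene order.

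Of the 36 measured genes on the Nrf2 target list, 21 fell over all genes tested and 23 adjusted over the list alone. Besides those named, Me1, which makes NADPH (-0.61 ± 0.04), Gstm1 (-0.59 ± 0.06), Ces1g, a carboxylesterase (-0.54 ± 0.10), Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis (-0.38 ± 0.04), Hmox1 (-0.32), Txnrd1 (-0.32) and Nqo1 (-0.26) fell. Slc7a11, the cystine transporter, stood at 0.09, Srxn1 at -0.15 and the ferritin gene Fth1 at 0.04 without passing. The list as a whole was lower (camera, adjusted p = 7.3e-22), also with an estimated correlation (adjusted p = 2.6e-05). It was also lower in the 7 ages whose arrays had a trimmed mean of 500 (13 fell, adjusted p = 0.0011 with an estimated correlation) and at PND1 to PND4 alone (19 fell, adjusted p = 0.0045 with an estimated correlation).

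Of the other antioxidant enzymes, 7 of 24 fell, such as Gsto1 (-0.46) and mitochondrial Sod2 (-0.19), and 9 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.01, and adjusted p = 0.64 with an estimated correlation). Among macrophage genes 5 of 13 fell (5 adjusted over the list alone, camera adjusted p = 0.023, and 0.64 with an estimated correlation). The scavenger receptor Marco averaged -0.48 (-1.90 at PND1 to PND4, 0.32 at other ages) and Siglecf, an alveolar macrophage marker, -0.40 (-1.09 and 0). Endothelial genes rose in 4 of 14, with Cdh5, the cadherin of vessel walls, at 0.40 and Tie1 at 0.23 (5 adjusted over the list alone, adjusted p = 0.74 with an estimated correlation). Clock genes rose in 4 of 14, led by Per1 (0.53 ± 0.08) and Cry2 (0.35), again 4 adjusted over the list alone (adjusted p = 0.64 with an estimated correlation). Sftpd, a surfactant protein, rose by 0.36 and Cebpa by 0.28 among 15 surfactant and type 2 cell genes (3 adjusted over the list alone, camera adjusted p = 0.74 with an estimated correlation). The Sftpd average mixes directions, higher in knockouts at E13.5, in libraries that stood apart, and lower at E18.5. Mki67 (-0.43) and Rrm2 (-0.43) fell among 21 cell cycle genes (5 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). Genes of squamous oesophagus, a neighbouring tissue, and of liver were lower with these groups (medians -0.51 and -0.86, adjusted p = 0.64 and 0.72 with an estimated correlation). In the liver list 0 of 6 passed (limma, 0 adjusted over the list alone).

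In all, 4754 probe sets passed the threshold in the average, 2391 higher and 2363 lower, and 19 of them by at least 2-fold. The even split depended on the scaling, with 13.8% of 4776 higher as deposited and 69.1% of 4471 with array medians subtracted. Of 35 lists tested, 12 passed, but 1 passed with an estimated correlation, and 7 passed without wild-type PND14 replicate 2. Fewer than 12 also passed without E13.5, where knockout libraries stood apart.

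**Figure D2:**
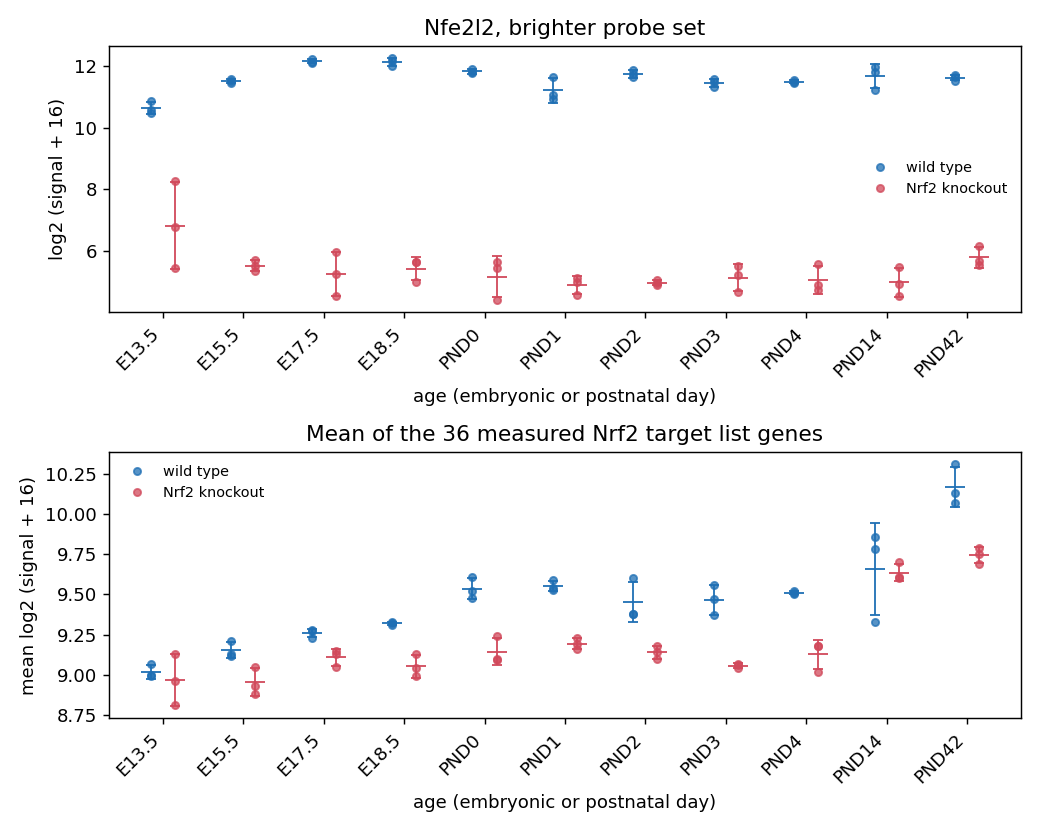
The upper panel plots the brighter Nfe2l2 probe set and the lower panel the mean of the 36 measured Nrf2 target genes (vertical axes, log2(signal + 16)) in each library against age, with wild type in blue, knockout in red and bars for the mean and SD of 3 libraries. For Nfe2l2 the knockout libraries lie at 4.41 to 8.26 and the wild-type libraries at 10.49 to 12.25.

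Whether the knockout effect depended on age was tested directly. It did for 12739 probe sets (7624 genes, limma F test). Scgb1a1, the secretory protein of club cells, had the widest range among the 10 genes with the smallest p, from 7.21 higher in knockouts at E13.5 to -1.63 at E18.5 (F test, adjusted p = 1.1e-12). C1galt1, an enzyme of O-glycosylation, ranged from -0.93 to 2.50 and lay at 2.08 to 2.50 at PND1 to PND4, and Trim68 lay at 1.77 to 2.75 at those ages. Trim34a did the opposite there, at -2.86 to -2.12. These ages form their own array set, so a difference between the sets is not excluded for C1galt1, Trim68 and Trim34a. Shisa2, which restrains Fgf and Wnt receptors, fell at PND0 (-2.62) while Spsb1 rose there (2.44). Gsta3 was at 1.26 at E13.5 and -0.57 at PND14, neither of which passed, and fell at every age from E18.5 to PND4 (-2.10 at E18.5, -2.82 at PND1, -2.30 at PND4) and at PND42 (-1.34).

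**Figure D3:**
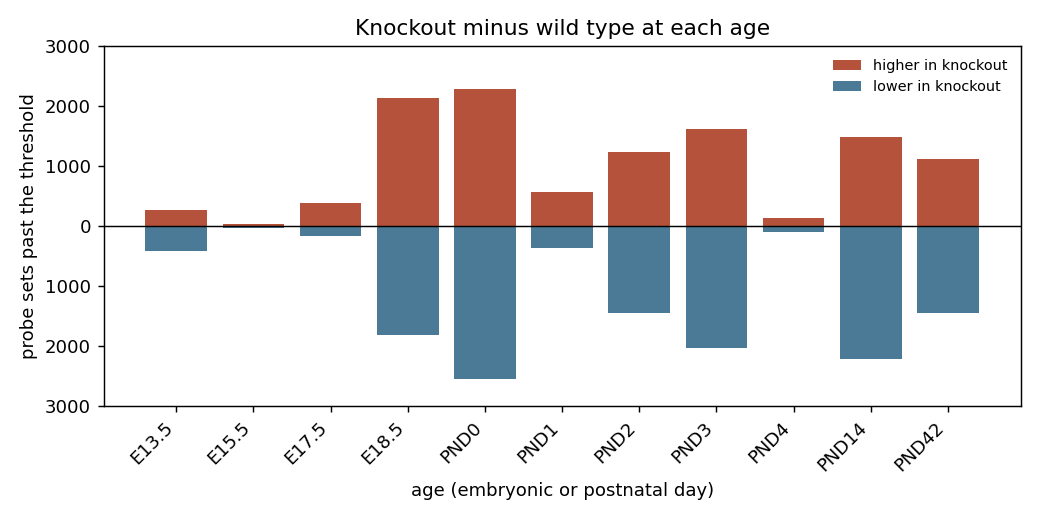
Bars give, for each age, how many probe sets passed the threshold higher (upward) and lower (downward) in knockout than in wild type, 3 libraries against 3. The totals run from 57 at E15.5 to 4834 at PND0.

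At E13.5 and E15.5, the ages of early airway branching, knockout libraries were compared with wild type for signs of a different start of lung development. At E13.5 the club cell gene Scgb1a1 was higher in knockouts by 7.21 ± 0.50 (SE, n = 3 per group, limma, adjusted p = 6.2e-15). Inmt, a methyltransferase abundant in lung, was higher by 3.99 ± 0.47. These SEs come from the spread pooled over all groups and understate that of the knockout libraries here. The SD was 2.25 in knockouts and 1.6 in wild type for Scgb1a1, and 2.22 and 0.19 for Inmt. Of 10 club cell genes 6 rose, with the P450 gene Cyp2f2 at 3.92 and haptoglobin, Hp, at 3.42, and 9 rose adjusted over the list alone (camera adjusted p = 5.9e-22, and 5e-04 with an estimated correlation). Type 1 cell genes rose in 6 of 14, with Ager at 2.30 and the water channel Aqp5 at 1.72 (10 adjusted over the list alone). Surfactant and type 2 cell genes rose in 5 of 15, with Sftpd at 2.91 and Sftpa1 at 2.53 (8 rose and 1 fell adjusted over the list alone). Both list calls were lost with an estimated correlation (adjusted p = 0.18 for each). Matrix genes fell in 3 of 14, among them elastin, Eln (-1.28), and tenascin C, Tnc (-1.05), and 5 adjusted over the list alone (adjusted p = 0.19 with an estimated correlation). Wild-type replicate 2 stood apart in the mean of this list (12.62 against 12.18 and 12.07) and of lists of other tissues: cartilage (10.01 against 8.47 and 7.73), skeletal muscle (10.32 against 8.46 and 8.29) and liver (10.31 against 7.20 and 7.28). The 3 knockout libraries were not alike: Scgb1a1 stood at 14.76, 10.50 and 13.87, and replicate 1, the highest, was also highest in Nfe2l2 (8.26).

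At E13.5, 692 probe sets passed, 273 higher and 419 lower (39.5% higher, 24.9% as deposited and 51.2% with array medians subtracted). The count was 353, 351 and 1693 without wild-type replicates 1, 2 and 3 and 325 without knockout replicate 2. It was 1102 with arrays scaled to a trimmed mean of 500. With those 6 libraries alone in the fit, 0 passed in limma and 4102 had an unadjusted p under 0.05.

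At E15.5, Scgb1a1 (4.21 ± 0.50, adjusted p = 7.7e-07) and Inmt (2.91 ± 0.47) were again higher in knockouts, and 1 Zfp142 probe set fell (-1.85 ± 0.25, none of 6 others passed). None of the 36 Nrf2 target genes passed over all genes tested, and 3 fell adjusted over the list alone (camera adjusted p = 0.0029, and adjusted p = 0.68 with an estimated correlation). In all 57 probe sets passed, 27 higher and 30 lower, against 2820 with an unadjusted p under 0.05. The count was 37, 35 and 32 without wild-type replicates 1, 2 and 3, 30 without knockout replicate 3, 116 with those 6 libraries alone in the fit and 949 with array weights.

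At E17.5 and E18.5, the stages before birth when airspaces form, the question was whether knockout lungs matured like wild type. In the knockout libraries labelled E17.5, Chil3, a chitinase-like protein of alveolar macrophages (4.31 ± 0.56, SE, n = 3 per group, adjusted p = 1.1e-06), and Pon1, a paraoxonase (3.46 ± 0.46), were higher than in wild type. Macrophage genes rose in 5 of 13, with Marco at 3.06 and lysozyme, Lyz2, at 1.65 (5 adjusted over the list alone, adjusted p = 0.0048 with an estimated correlation). Interferon-response genes rose in 2 of 13 over all genes and 9 adjusted over the list alone (adjusted p = 0.023 with an estimated correlation). Inflammation genes rose in 4 of 15, with lipocalin, Lcn2, at 2.16 (4 adjusted over the list alone, adjusted p = 0.041 with an estimated correlation). Gstp1 (-0.52) was the only Nrf2 target to fall over all genes tested, with 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Oesophagus genes fell in 2 of 8, including Krt4 (-4.56 ± 1.02, or -4.12 with adjusted p = 0.087 without knockout replicate 2), and in 7 adjusted over the list alone (adjusted p = 0.085 with an estimated correlation). Liver genes were higher with these groups (median 3.33). Of 6 none passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.0025, and adjusted p = 0.43 with an estimated correlation). The list mean was 8.34, 8.79 and 7.74 in the knockout libraries and 5.29, 4.98 and 4.94 in wild type.

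At E17.5, 550 probe sets passed, 380 higher and 170 lower. The count was 333, 258 and 359 without wild-type replicates 1, 2 and 3, 257 and 261 without knockout replicates 2 and 3, and 1922 with those 6 libraries alone in the fit. It was 827 with array medians subtracted and 3072 with array weights.

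In the knockout libraries labelled E18.5, cell cycle genes rose in 16 of 21, with Birc5 at 1.48, Bub1 at 1.42 and the replication gene Mcm2 at 1.42 (20 adjusted over the list alone, camera adjusted p = 9.4e-11, and adjusted p = 0.34 with an estimated correlation). Type 1 cell genes fell in 7 of 14 and rose in 2, with Rtkn2 at -2.26 and Aqp5 at -2.10 (9 fell and 2 rose adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Sftpd (-2.04) was 1 of 3 surfactant and type 2 cell genes of 15 to fall (6 adjusted over the list alone, adjusted p = 0.44 with an estimated correlation). Scgb1a1 (-1.63) was 1 of 3 lower club cell genes of 10 (4 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Hypoxia-response genes fell in 4 of 12, including Ankrd37 (-1.07), Bnip3 (-0.82) and Vegfa (-0.80), 5 adjusted over the list alone, and kept their call with an estimated correlation (adjusted p = 0.045). Crh, corticotropin-releasing hormone, rose (3.62 ± 0.34, adjusted p = 1.2e-10) and Pon1 fell (-3.07 ± 0.46). Nrf2 targets fell in 5 of 36 and rose in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Cartilage genes moved with these groups, 2 of 8 higher and 7 adjusted over the list alone (adjusted p = 0.34 with an estimated correlation). The cartilage collagen gene Col2a1 stood at 13.02 in knockout replicate 1 against 8.78 and 8.62 in the others. Its rise (3.69 ± 1.00) did not pass without that library (2.25, adjusted p = 0.27), without wild-type replicate 1 (adjusted p = 0.072) or without wild-type replicate 2 (adjusted p = 0.062).

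At E18.5, 3940 probe sets passed, 2126 higher and 1814 lower. The count was 2019 and 1651 without wild-type replicates 1 and 2, 1716 without knockout replicate 1, 1719 with those 6 libraries alone in the fit and 7009 with array weights. On a scale of 2486 genes that ran from 0 at wild-type E15.5 to 1 at wild-type PND0, the knockout libraries labelled E18.5 averaged 0.44 ± 0.09 (SD, n = 3) and those labelled E17.5 averaged 0.79 ± 0.05, whereas wild type rose from 0.59 ± 0.07 to 0.83 ± 0.12.

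**Figure D4:**
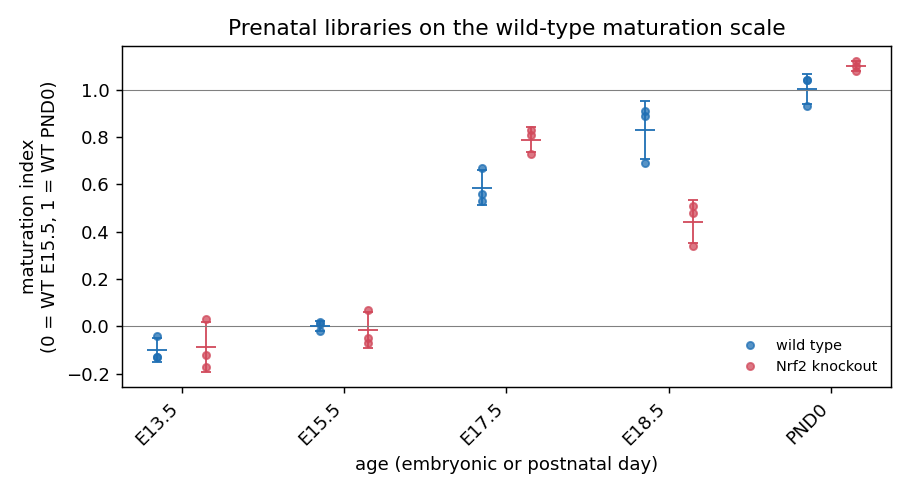
The maturation index (vertical axis, no unit, 0 for the wild-type E15.5 mean and 1 for the wild-type PND0 mean) is plotted for each library against age from E13.5 to PND0, with wild type in blue, knockout in red and bars for the mean and SD of 3 libraries. The knockout libraries labelled E18.5 lie at 0.34 to 0.51, below those labelled E17.5 at 0.73 to 0.83.

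On the day of birth the knockout effect on Nrf2 targets was wide. At PND0, 13 of 36 fell, including Gsta3 (-2.33), Me1 (-1.29) and Nqo1 (-0.84), and 15 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00065, and adjusted p = 0.18 with an estimated correlation). Clock genes rose in 6 of 14, with Per1 at 2.18 ± 0.28 (SE, n = 3 per group), Nr1d1 at 1.34 and Cry2 at 1.12 (8 adjusted over the list alone, adjusted p = 0.064 with an estimated correlation). Hypoxia-response genes rose in 5 of 12, with adrenomedullin, Adm, at 2.00 and Bnip3 at 1.15 (6 adjusted over the list alone, adjusted p = 0.064 with an estimated correlation). Immediate early genes rose in 5 of 14 and fell in 1, with Fos at 1.68 (8 and 1 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Genes of cholesterol and lipid synthesis fell in 7 of 13, with Idi1 at -0.96, squalene epoxidase, Sqle, at -0.84 and Hmgcs1 at -0.74 (8 fell and 1 rose adjusted over the list alone, adjusted p = 0.064 with an estimated correlation). Fam107a (3.68 ± 0.31, adjusted p = 7.7e-13) and the transcription factor gene Zbtb16 (3.12 ± 0.51) were among the largest rises. Thymus genes were lower with this group (median -1.31), 1 of 7 over all genes and 3 adjusted over the list alone (adjusted p = 0.98 with an estimated correlation). So were oesophagus genes (median -1.61, 2 of 8 adjusted over the list alone, adjusted p = 0.98 with an estimated correlation), with list means of 9.86, 7.33 and 8.49 in the knockout libraries and 10.28, 9.92 and 10.24 in wild type. The T cell gene Bcl11b stood at 11.12 in wild-type replicate 2 against 7.19 and 8.30. Its fall (-2.72 ± 0.81) did not pass without that library (-1.60, adjusted p = 0.32) or without knockout replicate 2 (adjusted p = 0.053) or 3 (adjusted p = 0.088). In all, 4834 probe sets passed, 2284 higher and 2550 lower, and 3113 without knockout replicate 3.

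PND1 to PND4 cover the first days of air breathing, and Nrf2 targets fell on each of them: 5, 6, 13 and 2 of 36 over all genes tested at PND1, PND2, PND3 and PND4. Adjusted over the list alone, 8 fell at PND1, 10 fell and 2 rose at PND2, 16 fell and 1 rose at PND3, and 7 fell and 1 rose at PND4. The list passed camera at each age (adjusted p = 9.9e-07, 0.00021, 1.4e-06 and 5.4e-08), and with an estimated correlation its adjusted p was 0.071, 0.29, 0.12 and 0.039. The counts below depended on the scaling of the arrays: as deposited, 284 probe sets passed at PND1, 1410 at PND2 (16% higher) and 128 at PND4 (26.6% higher), and with array medians subtracted 282, 1316 and 95. With array weights 1483 passed at PND1, 5814 at PND3 and 488 at PND4. Liver genes were lower with the Nrf2 targets at all 4 ages (list means of 9.30, 10.05, 9.93 and 7.65 in wild type and 6.34, 7.48, 5.54 and 5.43 in knockouts, adjusted p = 0.67, 0.63, 0.77 and 0.57 with an estimated correlation). Single wild-type libraries stood at 12.47, 14.36, 12.90 and 12.79, and knockout PND2 replicate 3 stood at 11.70. At PND4 wild-type replicates 1 and 2 stood at 4.99 and 5.16 and the knockouts at 5.13, 5.58 and 5.57. The lower liver mean of knockouts at PND4 thus rested on wild-type replicate 3. Gsta3 fell at all 4 ages, and Gpx2 at PND1 (-1.95), PND2 (-2.18) and PND3 (-1.34). Rbm45 was among the largest rises at PND1 (3.11 ± 0.25, SE, n = 3 per group, adjusted p = 4.1e-13) and PND4 (2.81 ± 0.25), as was H2-Ea, an MHC class II chain, at PND4 (3.31 ± 0.40).

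At PND1, hypoxia-response genes fell in 3 of 12 (4 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation). The clock genes Nr1d2 (-0.99) and Dbp (-0.93) fell among 14 (3 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). Marco fell (-2.04). Myl2, a heart muscle gene, stood at 14.43 in wild-type replicate 1 against 10.34 and 8.74, and its fall (-5.01 ± 1.21) did not pass without that library (-3.38, adjusted p = 0.18) or without knockout replicate 2 (adjusted p = 0.053). In all 925 probe sets passed, 563 higher and 362 lower. The count was 531 and 532 without wild-type replicates 2 and 3, 566 and 513 without knockout replicates 1 and 2, and 268 with those 6 libraries alone in the fit.

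At PND2, macrophage genes fell in 4 of 13, with Marco at -2.72 (5 adjusted over the list alone), while lymphocyte genes rose in 5 of 12, with Cd3d at 4.16 (7 adjusted over the list alone). Both calls had an adjusted p = 0.29 with an estimated correlation. Thymus genes moved with them, 4 of 7 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation). Rag1, needed to assemble antigen receptors, stood at 12.99, 9.53 and 12.37 in the knockout libraries. Prss16, a thymus protease gene, was among the largest rises (5.02 ± 0.98, adjusted p = 0.00087). Of the 2683 probe sets that passed, 1225 were higher and 1458 lower, and 1021 passed once 3 libraries with thymus transcripts were left out (knockout PND2 replicates 1 and 3, wild-type PND14 replicate 2). That choice was made after seeing the data. Wild-type PND14 replicate 3 and wild-type PND0 replicate 2 also held thymus transcripts (list means 9.39 and 9.37, against 9.25 in knockout PND2 replicate 3) and were kept in. The count was 1512 without wild-type replicate 2, 929 without knockout replicate 1, and 36 with the 6 libraries of this age alone in the fit.

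At PND3, skeletal muscle genes rose in 5 of 10 and liver genes fell in 2 of 6 (7 and 6 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation for each). These were unequal between libraries. The muscle gene Tnnc2 stood at 6.76, 14.07 and 10.75 in knockouts. Its rise (5.48 ± 1.51) did not pass without knockout replicate 2 (3.70, adjusted p = 0.18), knockout replicate 3 (adjusted p = 0.051) or wild-type replicate 1 (adjusted p = 0.064). The fetal liver gene Afp stood at 7.92, 14.03 and 11.82 in wild type. Its fall (-5.89 ± 1.66) did not pass without wild-type replicate 2 (-4.50, adjusted p = 0.15), wild-type replicate 3 (adjusted p = 0.067) or knockout replicate 1 (adjusted p = 0.06). Cell cycle genes fell in 5 of 21 (16 adjusted over the list alone, adjusted p = 0.77 with an estimated correlation). Genes of the endoplasmic reticulum stress response fell in 4 of 12, with Pdia4 at -1.45 (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.76 with an estimated correlation), as did other antioxidant enzymes in 5 of 24 (7 fell and 1 rose adjusted over the list alone, adjusted p = 0.77 with an estimated correlation). In all 3640 probe sets passed, 1610 higher and 2030 lower, and 2360 without knockout replicate 3. The count was 6175 as deposited (4.4% higher) and 1886 with array medians subtracted (32.8% higher).

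At PND4, Gsta3 (-2.30) and Gstm1 (-0.91) were the Nrf2 targets that fell over all genes tested. Macrophage genes fell in 1 of 13 over all genes and in 5 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). Lists of brown fat, which shares Fabp4 with the macrophage list, liver and heart muscle were lower with them (medians -1.87, -2.11 and -1.37, adjusted p = 0.32, 0.57 and 0.44 with an estimated correlation). The brown fat mean was 9.14, 6.98 and 7.78 in wild type and 6.67, 5.49 and 7.02 in knockouts, and the liver and heart means were both 12.79 in wild-type replicate 3. The airway secretory gene Scgb3a1 fell (-4.53 ± 1.01, SE, adjusted p = 0.015), with knockout libraries at 10.60, 8.80 and 8.16. It did not pass without wild-type replicate 1 (adjusted p = 0.078) or 3 (adjusted p = 0.061) or knockout replicate 2 (adjusted p = 0.086) or 3 (adjusted p = 0.14). Here 219 probe sets passed, 125 higher and 94 lower, with 128 without wild-type replicate 3 and 145 and 142 without knockout replicates 2 and 3.

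At PND14, during alveolar growth, cell cycle genes fell in 19 of 21, with topoisomerase Top2a at -2.27, and in all 21 adjusted over the list alone (camera adjusted p = 3.1e-23, and adjusted p = 0.17 with an estimated correlation). Ciliated cell genes rose in 7 of 13 (10 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Immediate early genes rose in 7 of 14, with Fos at 1.72 (10 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). P450 and other xenobiotic genes rose in 3 of 14, with Cyp1a1 at 3.12 ± 0.41 (SE, n = 3 per group, adjusted p = 1.2e-06; 3 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation). Thymus genes moved with these groups, 5 of 7 lower (6 adjusted over the list alone, camera adjusted p = 0.18 with an estimated correlation). Wild-type replicate 2, high in thymus genes, stood lowest in wild type in the ciliated list (7.30 against 8.49 and 7.91). The same held in the xenobiotic list (9.06 against 9.86 and 9.82). Rag1 stood at 8.49, 14.19 and 11.93 in wild type, and its fall (-4.77 ± 1.19) did not pass without wild-type replicate 2 (-3.44, adjusted p = 0.20) or knockout replicate 3 (adjusted p = 0.053). Without the 3 libraries with thymus transcripts, 642 probe sets passed in place of 3695 (1475 higher, 2220 lower), cell cycle genes fell in 5, immediate early genes rose in 4 (adjusted p = 0.032 with an estimated correlation) and 3 Nrf2 targets fell (adjusted p = 0.16 with an estimated correlation). The count was 7242 without wild-type replicate 1, 571 without wild-type replicate 2, 1440 without knockout replicate 3, and 1 with the 6 libraries of this age alone in the fit, where 3523 had an unadjusted p under 0.05 in limma. RNA quality may have differed too. The 3' minus 5' difference of the actin control was 0.687, 1.214 and 1.353 in the knockout libraries and 0.668, 0.549 and 0.616 in wild type. For the Gapdh control it was 0.739, 1.348 and 1.336 against 0.834, 0.279 and 1.028, and 555 probe sets passed with it as a covariate.

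At PND42, in the adult lung, 10 of 36 Nrf2 targets fell, with Ces1g at -2.41, Gpx2 at -2.26, Aox1 at -1.70, Gclc at -1.29 and Me1 at -1.25, and 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.8e-11, and 0.0055 with an estimated correlation). Gdpd3, a lysophospholipase D gene, fell (-5.16 ± 0.40, SE, n = 3 per group, adjusted p = 8.9e-14), and Fggy (2.31 ± 0.42) and the metallothionein gene Mt3 (2.02 ± 0.41) rose. The clock genes Dbp (1.17) and Nr1d2 (0.88) rose among 14 (3 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation). Marco (-1.70) was the macrophage gene of 13 that fell (1 adjusted over the list alone, adjusted p = 0.72 with an estimated correlation). In all 2557 probe sets passed, 1109 higher and 1448 lower, with 1702 and 1585 without knockout replicates 2 and 3 and 3969 with array weights. The 3' minus 5' difference of the actin control separated the genotypes, with 0.691, 0.65 and 0.673 in knockouts and 0.44, 0.432 and 0.42 in wild type, so RNA quality may have differed here as well. For the Gapdh control it was 0.421, 0.502 and 0.623 against 0.462, 0.068 and 0.201, and 2213 probe sets passed with it as a covariate.

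**Figure D5:**
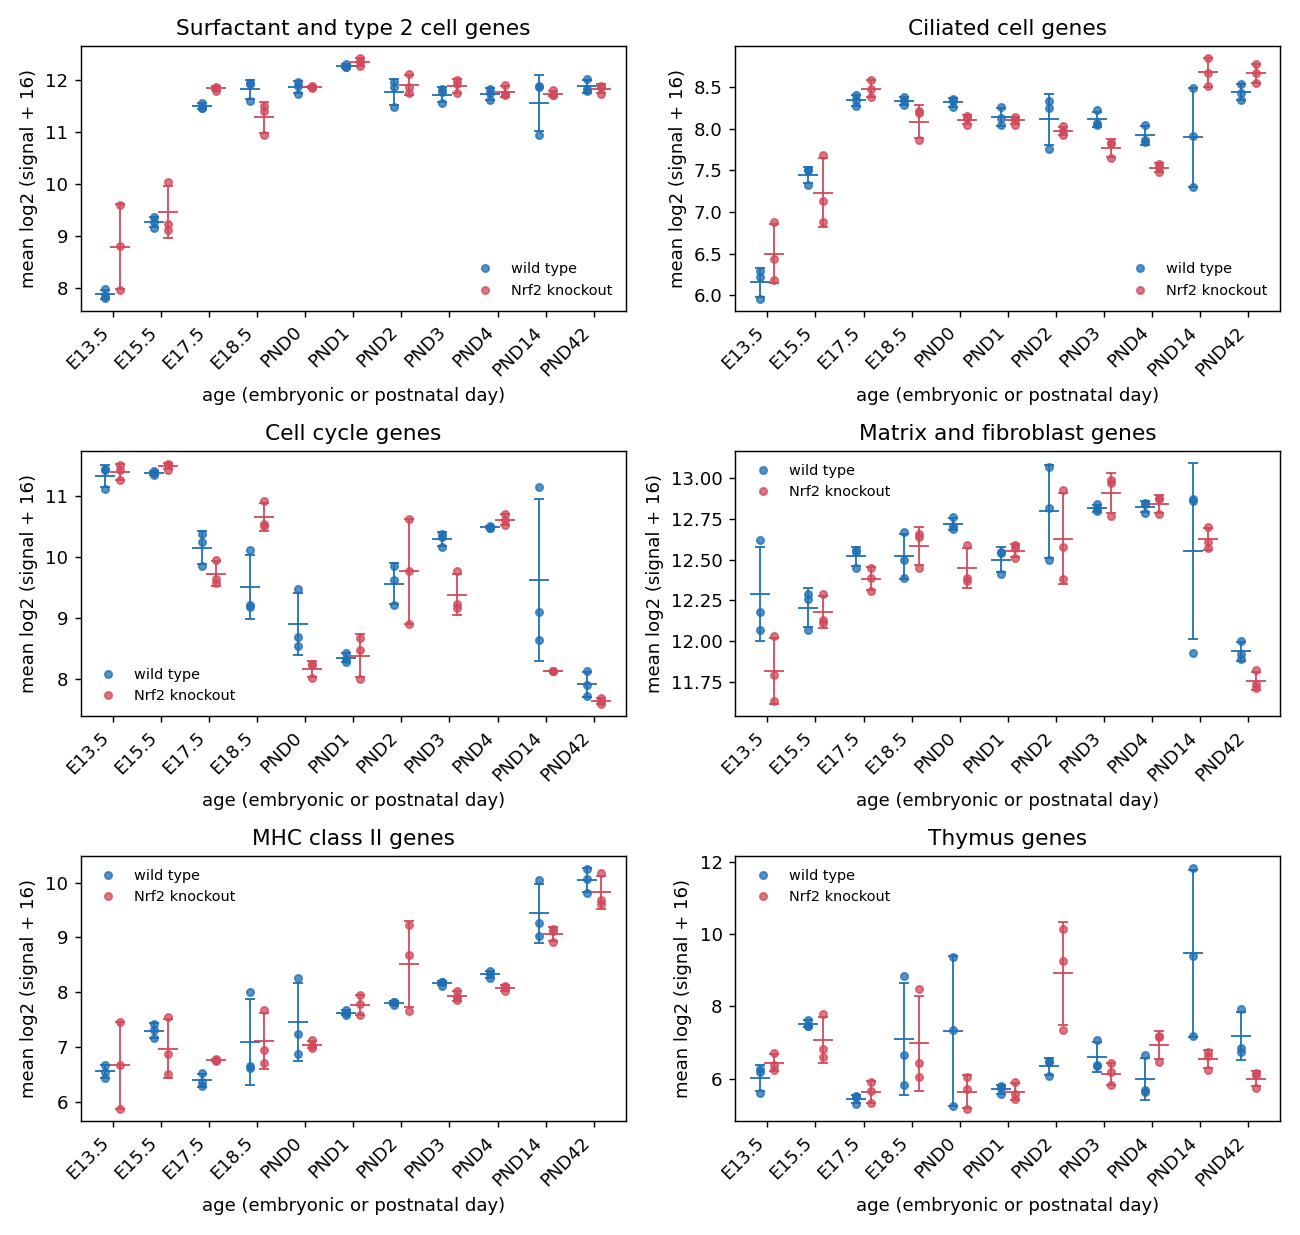
Each panel plots the mean of the measured genes of 1 list (vertical axes, log2(signal + 16)) in each library against age, with wild type in blue, knockout in red and bars for the mean and SD of 3 libraries. In the thymus panel wild-type PND14 replicate 2 stands at 11.82 and knockout PND2 replicate 1 at 10.15.

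In wild type, 29376 probe sets (13921 genes) differed between the 11 ages (limma F test), and the course was divided into 3 steps, from E13.5 to E18.5, from E18.5 to PND4 and from PND4 to PND42. Before birth, epithelial differentiation genes rose together. Scgb1a1 rose 404-fold (8.66 ± 0.50, SE, n = 3 per group, adjusted p = 6.1e-20), Retnla, a macrophage and epithelial secreted protein, by 8.52 ± 0.45, Slc34a2, the phosphate transporter of type 2 cells, by 7.30 ± 0.43, Sftpd by 6.70 ± 0.41 and Ager, a marker of type 1 cells, by 6.35 ± 0.34. All 10 club cell genes, 12 of 15 surfactant and type 2 cell genes, 10 of 13 ciliated cell genes such as the ciliary regulator Foxj1 (3.66), and 13 of 14 type 1 cell genes rose, with 1 type 1 cell gene lower. Adjusted over the list alone these counts were 10, 14, 10 and 13, and the lists kept their calls with an estimated correlation (adjusted p = 0.024, 0.024, 0.042 and 0.026). Hypoxia-response genes rose in 8 of 12 (8 adjusted over the list alone, adjusted p = 0.024 with an estimated correlation) and xenobiotic genes in 10 of 14 with 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.026 with an estimated correlation). All 14 endothelial genes rose and all 21 cell cycle genes fell, over all genes and adjusted over the list alone, but neither list held with an estimated correlation (adjusted p = 0.21 and 0.51). Among the largest falls were the embryonic globins Hbb-bh1 (-5.54 ± 0.45) and Hba-x (-5.52 ± 0.41) and the retinoid-binding Crabp1 (-5.12 ± 0.39). Afp also fell (-5.41 ± 1.66), but did not pass without wild-type E13.5 replicate 2 (-4.36, adjusted p = 0.069), the library high in liver genes. Cartilage genes fell with them in 7 of 8 (7 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation). In all 15800 probe sets passed, 7399 higher and 8401 lower.

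Across birth, from E18.5 to PND4, hypoxia-response genes fell in 7 of 12, including Ankrd37 (-3.58 ± 0.24, SE, n = 3 per group), Ndrg1 (-2.63 ± 0.18), the oxygen-sensing Egln3 (-2.61) and the glucose transporter Slc2a1 (-2.15), again 7 adjusted over the list alone (camera adjusted p = 5.1e-09, and 0.00021 with an estimated correlation). Because PND4 and E18.5 were in different array sets, the step was also taken to PND14, where 9 of these genes fell and 1 rose (adjusted p = 0.00011 with an estimated correlation). Imprinted and other embryonic growth genes fell in 8 of 19 and rose in 1, with Dlk1 at -2.76 and Igf2bp1 at -2.04 (8 and 1 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). Macrophage genes rose in 7 of 13 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Brown fat genes rose with them in 3 of 6 (3 adjusted over the list alone), with Ucp1 at 4.44 ± 1.14, but that list did not pass (camera adjusted p = 0.18). Its mean was 9.14, 6.98 and 7.78 at PND4 and 5.48, 5.77 and 7.20 at E18.5. Lymphocyte genes rose in 5 of 12, with the B cell gene Cd79a at 3.30 (5 adjusted over the list alone, adjusted p = 0.78 with an estimated correlation). Mast cell genes rose in 4 of 8, with the tryptase gene Tpsb2 at 2.79 (5 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). The list mean was 6.13 at wild-type PND0, 6.90 at PND1, 7.06 at PND4 and 5.90 at PND14, so it followed the array sets. Cell cycle genes rose in 14 of 21 (15 adjusted over the list alone, adjusted p = 0.78 with an estimated correlation). Tmem100, an endothelial gene of BMP signalling, rose by 3.47 ± 0.20, and the non-coding RNA Rian fell (-4.98 ± 0.34). A Rian probe set separated the array sets (8.14 at PND1 to PND4, 11.36 at E18.5, PND0 and PND14). The oesophagus genes Krt15 (-5.76 ± 0.88) and Krt13 (-5.11 ± 1.03) fell with this group, 5 of 8 in the list (7 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation), but Krt13 stood at 0.46 with PND14 in place of PND4. In all 13791 probe sets passed, 6870 higher and 6921 lower, and 8737 with PND14 in place of PND4. As deposited 25267 passed with 3% higher, so the even split depended on scaling.

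From PND4 to PND42, all 21 cell cycle genes fell, with Cdk1 at -3.61 and Rrm2 at -3.57 (21 adjusted over the list alone, camera adjusted p = 1.1e-14, and adjusted p = 0.32 with an estimated correlation). Embryonic growth genes fell in 12 of 19 and rose in 1, with Dlk1 at -3.78, Mest at -3.41 and Igf2 at -3.33 (13 and 2 adjusted over the list alone, adjusted p = 0.011 with an estimated correlation). From PND14 to PND42 6 fell and 1 rose (adjusted p = 0.19 with an estimated correlation). Matrix genes fell in 9 of 14 and rose in 1, with Tnc at -2.84 and Eln at -1.48 (9 and 1 adjusted over the list alone, adjusted p = 0.39 with an estimated correlation). Interferon-response genes rose in 11 of 13 and fell in 1, with Ifit3 at 3.89 ± 0.37 (SE, n = 3 per group; 11 and 1 adjusted over the list alone, adjusted p = 0.32 with an estimated correlation). MHC class II genes rose in 7 of 8, with H2-Ab1 at 3.00 (7 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Nrf2 targets rose in 20 of 36 and fell in 4, with Gsta3 at 2.97, Aox1 at 2.40, Ces1g at 2.29 and Gpx2 at 2.20 (21 and 4 adjusted over the list alone, adjusted p = 0.32 with an estimated correlation). The P450 gene Cyp2b10 (4.93 ± 0.49), Inmt (4.25 ± 0.47) and the glucocorticoid-responsive factor gene Klf9 (3.60 ± 0.27) were among the largest rises, and midkine, Mdk (-5.36 ± 0.22), and versican, Vcan (-3.75 ± 0.23), among the largest falls. In all 15326 probe sets passed, 7649 higher and 7677 lower, and 6647 passed from PND14 to PND42, within 1 array set. As deposited 23776 passed with 93.8% higher. Of 35 lists 9 passed, and 1 with an estimated correlation.

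The same steps were taken in knockouts. From E13.5 to E18.5, within 1 array set, 9734 probe sets passed in knockouts (4695 higher, 5039 lower), and 3656 of those higher and 3939 of those lower were called the same way in wild type, where independent lists would share 771 and 940. Across birth 14524 passed (7204 higher, 7320 lower), with 4300 and 4529 shared, and from PND4 to PND42 16285 passed (8133 higher, 8152 lower), with 5357 and 5552 shared. These 2 steps cross the array sets in both genotypes, so what they share also holds any difference between the sets. As deposited 26378 passed across birth with 3% higher, and 26413 from PND4 to PND42 with 93.3% higher. With array weights 14737 passed from E13.5 to E18.5. RNA quality moved with the step from PND4 to PND42: the Gapdh 3' minus 5' difference was -0.438, -0.542 and -0.25 at knockout PND4 and 0.421, 0.502 and 0.623 at knockout PND42. With it as a covariate 8862 passed in knockouts and 11709 in wild type.

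Whether a developmental change itself differed between genotypes was tested for each step. From E13.5 to E18.5, club cell genes rose less in knockouts: 7 of 10 had a lower step, with Scgb1a1 at -8.84 ± 0.71 (SE of the difference of differences, n = 3 per group, adjusted p = 1.9e-12), Cyp2f2 at -5.21 ± 0.60 and Hp at -4.82, and 9 adjusted over the list alone (camera adjusted p = 5.7e-14, and 0.012 with an estimated correlation). Surfactant and type 2 cell genes had a lower step in 8 of 15, with Sftpd at -4.95 (11 adjusted over the list alone). Type 1 cell genes had one in 9 of 14, with Aqp5 at -3.82 (11 lower and 2 higher adjusted over the list alone). Both list calls were lost with an estimated correlation (adjusted p = 0.11 for each). Inmt had a lower step as well (-6.44 ± 0.66). The step started from knockout E13.5 libraries that stood apart, with club cell list means of 10.65, 7.91 and 9.59 against 6.91 to 6.95 in wild type. Cartilage genes had a higher step in 5 of 8 (7 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). In all 2796 probe sets passed, 1358 higher and 1438 lower. The count was 1680 without wild-type E18.5 replicate 2, 1692 without knockout E18.5 replicate 1, 1148 with those 12 libraries alone in the fit, and 124 with E17.5 in place of E18.5, where 2 club cell genes had a lower step (adjusted p = 0.028 with an estimated correlation).

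Across birth, H2-Ea (3.63 ± 0.57, SE, n = 3 per group, adjusted p = 6.4e-05), Slc13a4, a sulfate transporter gene (3.43 ± 0.61), and Slfn4 (3.04 ± 0.61) had a higher step in knockouts and Crh (-3.95 ± 0.48) a lower one. With E17.5 in place of E18.5, Slc13a4 stood at -1.21, Slfn4 at -1.38 and Crh at 1.85. Type 1 cell genes had a higher step in 3 of 14 (8 higher and 2 lower adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). Cartilage genes had a lower one in 3 of 8 (4 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). In all 1201 probe sets passed, 621 higher and 580 lower. The count was 497, 474 and 2198 without wild-type E18.5 replicates 1, 2 and 3, 590 without wild-type PND4 replicate 3, 497 without knockout E18.5 replicate 1 and 669 without knockout PND4 replicate 2. It was 5386 with PND14 in place of PND4, 361 with E17.5 in place of E18.5, 563 with array medians subtracted and 3306 with array weights. Of 35 lists 10 passed, and with an estimated correlation 0 passed in limma's camera (2 at an unadjusted p under 0.05).

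From PND4 to PND42, Scgb3a1 (5.91 ± 1.43, SE, n = 3 per group, adjusted p = 0.01) and Clstn2 (3.08 ± 0.48) had a higher step in knockouts, and Gdpd3 (-5.08 ± 0.56) and H2-Ea (-3.12 ± 0.57) a lower one. Thymus genes had a lower step with them (1 of 7 called, and 1 adjusted over the list alone, adjusted p = 0.83 with an estimated correlation), led by Rag1 (-7.24 ± 1.68), which stood at 0.83 from PND14 to PND42. In all 1518 probe sets passed, 588 higher and 930 lower, with 954 without knockout PND42 replicate 3, 544 with PND14 in place of PND4, 2775 with array weights and 2369 with those 12 libraries alone in the fit. Of 35 lists 4 passed, and the number was 8 without wild-type PND4 replicate 2, 2 without wild-type or knockout PND42 replicate 1 and 7 without knockout PND42 replicate 3. With an estimated correlation 0 passed in limma's camera, and 0 had an unadjusted p under 0.05.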

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

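The tests of liver or thymus RNA, of other tissue at E18.5, of older lung RNA, of slower maturation and of earlier maturation of every lung, the versions that decided on genetic background and on age itself, and the comparison of PND1 to PND4 with the other ages were chosen only after the result was seen.

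The results below stood out because the knockout effect differed between ages or between steps, by a test of that difference. The knockout effect depended on age for 12739 probe sets (F test, highest other split 1293). The step from E13.5 to E18.5 differed between genotypes for 2796 probe sets (highest other split 1950), the step across birth for 1201 (highest other split 2035) and the step from PND4 to PND42 for 1518 (highest other split 1137). Chance allocation of single libraries can be excluded for each, since 1, 1, 2 and 1 of 100 splits gave as many, the real one included. These splits moved single libraries within an age. A difference that all 3 libraries of a group shared for another reason than genotype is therefore not excluded, here or in the splits below. For the step across birth 1 other split gave more than the real one.

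The range of the knockout effect over the 11 ages, on the log2 scale, was 8.84 for Scgb1a1, 3.94 for Aox3, 3.44 for Shisa2, 3.43 for C1galt1 and 3.38 for Trim34a. It was 3.23 for Trim68, 2.83 for Spsb1, 2.69 for Ampd3, 2.23 for Tmem14c and 1.41 for Ncbp2.

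For the average over ages 1 of 100 splits, the real one, gave as many as 4754 (highest other 189). For age in wild type 1 of 100 gave as many as 29376 (highest other 14634). Chance allocation of single libraries can be excluded for both. For single ages and for single steps in one genotype the 10 splits of 6 libraries are too few for a share under 0.05. The real counts and the highest others were 692 and 207 at E13.5, 57 and 4 at E15.5, 550 and 0 at E17.5, and 3940 and 154 at E18.5. They were 4834 and 0 at PND0, 925 and 15 at PND1, 2683 and 154 at PND2, 3640 and 2 at PND3, and 219 and 3 at PND4. They were 3695 and 2463 at PND14 and 2557 and 5 at PND42. For the 3 wild-type steps they were 15800 and 292, 13791 and 15, and 15326 and 3, and for the 3 knockout steps 9734 and 422, 14524 and 3, and 16285 and 4.

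The knockout effect at PND1 to PND4 differed from that at the 7 other ages for 5066 probe sets (2543 higher, 2523 lower, 434 by at least 2-fold). Chance allocation of single libraries can be excluded, with 1 of 100 splits as large (highest other 546). For the 434 the tables argue against scaling, since at least 91.9% of them kept call and sign under 3 other scalings. They were picked for their size, so this does not cover all 5066. In all, 5029 probe sets passed as deposited, 4804 with a trimmed mean of 500 and 3547 with array medians subtracted. Liver or thymus RNA stays a candidate explanation: with Alb and Rag1 levels in the model 216 of the 434 (49.8%) kept both, the median size went from 1.35 to 0.93 and 4067 probe sets passed in all in place of 5066 (3 versions were run, and splits by variation between replicates were not used because such a split by itself affects the outcome). Different genetic backgrounds of the mice behind the 2 array sets stay open. Of 194 genes 18.0% had another called gene within 2 measured genes (95th percentile of draws 8.2%), and the 22 less variable genes had 0 (median of draws 0). After that result a window of 50 genes was tried, with 40.9% of the 22 (95th percentile 27.3%) and 73.7% of the 194 (70.6%). C1galt1, Trim34a, Trim68 and H2-Ea, named above for these ages, belonged to this pattern. They stood at 2.26, -2.51, 2.20 and 3.17 at PND1 to PND4 and at -0.36, 0.02, -0.01 and -0.01 at the other ages. So did Aox3, Gsta3 and Rbm45 (-1.66, -2.45 and 3.03 against -0.40, -0.84 and 1.51). A background difference stays open for all these genes too. In wild type, a C1galt1 probe set stood at 7.46 at PND1 to PND4 and at 9.49 at E18.5, PND0 and PND14. Another differed by 0.22. An effect of age itself stays open too, because the array sets follow age and the correlations across genes of PND0 with PND1 (-0.10) and PND4 with PND14 (-0.12) lay inside the range of adjacent ages within a set (-0.29 to 0.29), by a criterion that was changed once, though without E18.5 that range was 0.06 to 0.29, above both.

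The knockout libraries labelled E18.5 lay earlier on the wild-type maturation scale (0.34, 0.51 and 0.48) than those labelled E17.5 (0.73, 0.83 and 0.81). The tables argue against tissue without epithelium as the whole cause, since its RNA would dilute all epithelial genes alike. From knockout E17.5 to E18.5 as labelled, 37 epithelial genes that rise with age differed from 18 that do not by -0.71 ± 0.17 (SD, n = 3). A first version on the rising genes alone was not used because dilution lowers them too. The test cannot decide on tissue with its own epithelium, such as oesophagus, which could supply the 18 genes too. The oesophagus list stood at 8.56, 6.49 and 8.31 in knockout libraries labelled E18.5 and at 6.24, 5.76 and 6.61 in those labelled E17.5. The tables also argue against slower maturation with every age as labelled. The mean index of knockout libraries labelled E17.5 stood 0.20 above that of wild type of that age (0.73 to 0.83 against 0.53 to 0.67). A first version, the change of -0.35 from E17.5 to E18.5, restated the pattern and was not used. An exchange of the 2 knockout groups is a candidate explanation: with their labels exchanged 477 probe sets passed against wild type at the 2 ages together, and 4490 as labelled. Differences in the staging of litters were not tested and stay open.

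Knockout libraries at E13.5 held transcripts that wild-type lung made only later. RNA of older lung is a candidate explanation that the test did not decide: the medians of 56 such genes stood 1.86, -0.09 and 0.66 above wild type in replicates 1, 2 and 3. Nfe2l2 stood at 9.01%, 0.84% and 2.87% of its signal in older wild-type lung and these genes at 9.39%, -0.24% and 1.52%, and replicate 1 had 98.2% of them above all wild type and an Nfe2l2 signal of 291 (highest knockout library of the other ages 55). The tables argue against earlier maturation of every lung, since genes that fall early in wild type stood 1.30 above where the wild-type course lies at the same rise of late genes (SD of wild-type libraries 0.53). Earlier maturation of some of the lungs combined in a sample stays open, since these 156 genes had medians of -0.27, -0.57 and -0.32, and single wild-type libraries had -0.23, 0.60 and -0.38 (this test and that of older lung RNA were each also run in another version on libraries picked by their values, which was not used). The Nfe2l2 signals argue against such maturation as the whole cause in replicates 1 and 3. They were 291 and 93, and no knockout library of the other, later ages passed 55.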

How the results depend on the processing

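Tests after scaling to a trimmed mean of 500, on subsets of ages or libraries and with other end ages of the steps were chosen only after the result was seen. For each value given below that moved, the cause was not tested, except that 1 probe set per gene, left-out libraries and subsets of ages test fewer probe sets or samples. Signal over background limits what can be seen: adding 16 to each signal understates changes of dim genes.

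Of 168 named values, 168 kept direction and call without the intensity trend, with the replicate block, with 1 probe set per gene and scaled to a trimmed mean of 500. As deposited and with medians subtracted 166 kept both, with pseudocounts of 1 or 64 165, with array weights or the Xist level 166, and with the robust model or the Gapdh difference 167. Without the dimmest 40% of probe sets 149 of 149 tested kept both, and with only the compared groups 114 of 134. Fewer kept both with PND14 in place of PND4 (34 of 60, with 7 reversed), E17.5 in place of E18.5 (50 of 60, with 4 reversed) and PND1 to PND4 alone (18 of 34). The counts were 30 of 34 for the 7 ages of 1 scale alone, 33 without E13.5, 34 without E17.5 and E18.5, and 38 of 42 without the 3 libraries with thymus transcripts. The fit of only the compared groups was not run for the average over ages or the dependence on age, where it equals the fit reported, nor were lists tested with array weights or the robust model.

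The Nfe2l2 difference ranged from -6.29 to -6.17 without single libraries. The replicate block, the number 1 to 3 as a block, gave 4813 for the average and moved no count. Of 33 pairings of numbers 1 had a correlation over 0.1 (range -0.18 to 0.21), and 27 of 66 libraries correlated best with their own number, so the numbers do not pair the samples.

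As deposited, counts were 284 at PND1, 1410 at PND2, 6175 at PND3 and 128 at PND4, 25267 and 23776 for the wild-type steps across and after birth, and 26378 and 26413 for the knockout ones. The wild-type steps had 18 and 16 lists. With array medians subtracted they were 827 at E17.5, 282 at PND1, 1316 at PND2, 1886 at PND3, 95 at PND4 and 563 for the difference across birth, with 14 lists after birth. Scaled to a trimmed mean of 500, E13.5 had 1102 and the wild-type step across birth 7 lists. Without the dimmest 40% of probe sets that step had 4 lists. With array weights counts were 949 at E15.5, 3072 at E17.5, 7009 at E18.5, 1483 at PND1, 5814 at PND3, 488 at PND4, 3969 at PND42. They were 14737 for the knockout step before birth, and 3306 and 2775 for the differences across and after birth. With only the compared groups they were 0 at E13.5 (limma, 4102 at an unadjusted p under 0.05), 116 at E15.5, 1922 at E17.5, 1719 at E18.5, 268 at PND1, 36 at PND2, 1 at PND14 (limma, 3523 at an unadjusted p under 0.05). They were 1148 and 2369 for the differences before and after birth, with 14 lists for the wild-type step after birth and 10 for its difference. With the Gapdh 3' to 5' difference as a covariate they were 555 at PND14 and 8862 for the knockout step after birth.

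Analysis of 1 probe set per gene, which tests fewer probe sets, gave 2137 for the average, 412, 34, 347, 2590, 2911, 534, 1092 and 2239 at E13.5 to PND3, 1812 at PND14, and 793 at PND42. It gave 8551, 5967 and 7217 for the wild-type steps, 5698, 6310 and 7590 for the knockout steps, 404 for the difference after birth, 6778 for the dependence on age and 13524 for age in wild type.

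The 7 ages of 1 scale alone gave 3072 for the average, and PND1 to PND4 alone 1538 for the dependence on age. Without E13.5 the average had 6 lists. Without the 3 libraries with thymus transcripts PND2 had 1021 and PND14 642. With PND14 in place of PND4, counts were 8737 and 6647 for the wild-type steps, 5386 for the knockout step after birth, and 5386 and 544 for the differences across and after birth, with 15 and 10 lists after birth for wild type and the difference. With E17.5 in place of E18.5 they were 124 and 361 for the differences before and across birth, with 16 lists across birth. With an estimated correlation, 1 list passed for the average, 6, 1 and 1 for the wild-type steps and 1, 0 and 0 for the differences (camera). Where 0 passed, 2 lists had an unadjusted p under 0.05 for the difference across birth and 0 for that after birth.

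With PND14 in place of PND4, values that changed sign were Prokr2 (-0.05), Krt13 (0.46), Krt4 (0.62) and Clec2d (0.27) in the wild-type step across birth, Pik3cd (-0.19) after birth, and Sult1d1 (-0.97) and Rag1 (0.83) in the difference after birth. With E17.5 in place of E18.5 they were Nefl (-0.24) in the difference before birth and Slc13a4 (-1.21), Slfn4 (-1.38) and Crh (1.85) across birth.

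Leaving out 1 library at a time, counts ranged from 4427 to 5403 for the average, 11705 to 14685 for the dependence on age and 28908 to 29495 for age in wild type. At E13.5 they ranged from 325 (without knockout replicate 2) to 1693 (wild-type replicate 3), with 353 and 351 without wild-type replicates 1 and 2. At E15.5 the range was 30 (knockout replicate 3) to 53, with 37, 35 and 32 without wild-type replicates 1, 2 and 3. At E17.5 it was 257 (knockout replicate 2) to 380, with 261 without knockout replicate 3 and 333, 258 and 359 without wild-type replicates 1, 2 and 3. At E18.5 it was 1651 (wild-type replicate 2) to 4847, with 2019 without wild-type replicate 1 and 1716 without knockout replicate 1. At PND0 it was 3113 (knockout replicate 3) to 4305. At PND1 it was 513 (knockout replicate 2) to 739, with 566 without knockout replicate 1 and 531 and 532 without wild-type replicates 2 and 3. At PND2 it was 929 (knockout replicate 1) to 2903, with 1512 without wild-type replicate 2, and at PND3 2360 (knockout replicate 3) to 3054. At PND4 it was 128 (wild-type replicate 3) to 192, with 145 and 142 without knockout replicates 2 and 3. At PND14 it was 571 (wild-type replicate 2) to 7242 (wild-type replicate 1), with 1440 without knockout replicate 3. At PND42 it was 1585 (knockout replicate 3) to 2470, with 1702 without knockout replicate 2.

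For the differences between steps the ranges were 1680 (wild-type E18.5 replicate 2) to 3351 before birth, with 1692 without knockout E18.5 replicate 1, and 954 (knockout PND42 replicate 3) to 1570 after birth. Across birth the range was 474 (wild-type E18.5 replicate 2) to 2198 (wild-type E18.5 replicate 3), with 497 without wild-type or knockout E18.5 replicate 1, 590 without wild-type PND4 replicate 3 and 669 without knockout PND4 replicate 2. Lists ranged from 7 (wild-type PND14 replicate 2) to 13 for the average. For the difference after birth they ranged from 2 (wild-type or knockout PND42 replicate 1) to 8 (wild-type PND4 replicate 2), with 7 without knockout PND42 replicate 3. In all, 22 of 168 named values lost their call without some library.

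The share of calls that were higher moved by over 10 points with scaling. As deposited, it went from 50.3% to 13.8% for the average, 39.5% to 24.9% at E13.5, 69.1% to 56.6% at E17.5, 45.7% to 16% at PND2, 44.2% to 4.4% at PND3, and 57.1% to 26.6% at PND4. It went from 49.8% to 3% and 49.9% to 93.8% for the wild-type steps across and after birth, 48.2% to 60.6%, 49.6% to 3% and 49.9% to 93.3% for the knockout steps, and 51.7% to 23.7% and 38.7% to 62% for the differences across and after birth. With medians subtracted it was 69.1% for the average, 51.2% at E13.5, 85.7% at E17.5, 66% at E18.5 (from 54%), 63.9% at PND2, 32.8% at PND3, and 52.6% at PND14 (from 39.9%). It was 33.5% for the wild-type (from 46.8%) and 27.7% for the knockout step before birth, and 39.8% for the difference across birth. Scaled to a trimmed mean of 500 the knockout step before birth had 58.8%. The median of all probe sets then moved by over 0.1: as deposited to -0.20 at PND3, -0.74 and -0.83 across birth in wild type and knockout, 0.64 and 0.77 after birth and 0.12 in its difference, with medians subtracted to 0.11 at PND2, -0.19 and -0.20 before and 0.16 and 0.15 across birth, and scaled to 500 to -0.14 after birth in wild type.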

Other observations

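The comparison of wild-type libraries between the array sets was chosen only after the result was seen, among the tests reported here, and the genes named in the next 2 paragraphs were picked after their values were seen.

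Mast cell genes differed between PND4 and both E18.5 and PND42 in wild-type lung, and both steps cross the array sets. Across birth the protease genes Mcpt4 (2.20 ± 0.35, SE, n = 3 per group) and Cma1 (1.68 ± 0.37) rose with Tpsb2. From PND4 to PND42, 4 of 8 fell and 1 rose (4 and 1 adjusted over the list alone): Cpa3 (-3.09 ± 0.38), Tpsb2 (-2.80 ± 0.40), Mcpt4 (-2.09 ± 0.35) and Cma1 (-1.88 ± 0.37). The list did not pass in that step (camera adjusted p = 0.083, and 0.36 with an estimated correlation). The list mean was 6.90 to 7.06 at wild-type PND1 to PND4, 6.13 at PND0 and 5.90 at PND14, and the Tpsb2 probe set was among those that separated the sets (2.72), so a difference between the sets is not excluded. Mesothelial genes went separate ways before birth. Mesothelin, Msln, rose by 5.71 ± 0.25 and the developmental regulator Wt1 fell (-1.37 ± 0.23), with 2 of 7 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.55). Msln then fell across birth (-1.91 ± 0.25), and Gpm6a rose from PND4 to PND42 (2.77 ± 0.24), again in steps that cross the sets.

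Lipid and sterol synthesis genes also moved apart before birth. The desaturase gene Scd1 (4.11 ± 0.41, SE, n = 3 per group), the fatty acid synthase gene Fasn (1.22 ± 0.13) and their regulator gene Srebf1 (1.11 ± 0.14) rose. The sterol synthesis genes Dhcr7 (-1.52 ± 0.26), Sqle (-1.34 ± 0.17), Idi1 (-0.80 ± 0.18) and Fdft1 (-0.73 ± 0.11) fell. In all 4 of 13 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.91).

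In knockout lung, embryonic growth genes fell in 12 of 19 from PND4 to PND42 (13 adjusted over the list alone, adjusted p = 0.0016 with an estimated correlation). Across birth hypoxia-response genes fell in 7 of 12 and rose in 2 (7 and 3 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation). From E13.5 to E18.5, surfactant and type 2 cell genes rose in 12 of 15, type 1 cell genes in 12 of 14 and club cell genes in 7 of 10 (12, 12 and 7 adjusted over the list alone). These 3 list calls were lost with an estimated correlation (adjusted p = 0.055, 0.065 and 0.20).

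Genes beside Nfe2l2 were tested for a chromosome segment carried along with the knockout allele. Of the 100 measured genes around it, 3% passed with at least 1.5-fold on average: Rbm45 (2.06 ± 0.07), Fam171b (-0.97 ± 0.10) and Cyct (-0.74 ± 0.11). Among 10000 random windows the median was 0, the 95th percentile 1% and the highest 3% (permutation test over windows, p = 0.0051). Such a segment is a candidate explanation, and an effect of the allele on its neighbours was not tested.

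Between the array sets, 376 probe sets separated the 12 wild-type libraries of PND1 to PND4 from the 9 of E18.5, PND0 and PND14 by at least 4-fold, 230 higher and 146 lower. Of 277 with another probe set of the same gene, 221 (79.8%) had one that differed by less than 0.5, among them Golt1b (-4.36), Sox4 (4.17), Epb41l2 (3.61) and S1pr3 (3.49).

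Markers of other tissues were high in single libraries. The mean of the liver list was 14.36 in wild-type PND2 replicate 2, 12.90 in wild-type PND3 replicate 2, 12.79 in wild-type PND4 replicate 3 and 12.47 in wild-type PND1 replicate 2. Among knockouts it was highest in PND2 replicate 3, at 11.70. That of the skeletal muscle list was 12.56 in knockout PND3 replicate 2, and that of the thymus list 11.82 in wild-type PND14 replicate 2. Array weights ran from 0.14 for wild-type PND14 replicate 2 to 3.1 for wild-type PND14 replicate 3.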
